A study of Corynebacterium glutamicum R with 2 samples.

How the data were processed

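Both samples were GntR1-FLAG immunoprecipitations from C. glutamicum R, and they formed a single group of 2 biological replicates per the labels. Per the labels' protocols, cells were treated with 1% formaldehyde, the DNA was sheared to 200 to 500 bp, and the immunoprecipitated and reference DNA were ligated to linkers, amplified by PCR and labelled with Cy5 and Cy3. The dye orientation was the same on both arrays, so a dye effect common to them does not cancel. Amplification by PCR and the labelling step can each change the ratio at a probe, and neither can be separated from the recovery of DNA by the resin.

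The deposited scanner files hold spot intensity values on a linear scale in both channels, made with Agilent Feature Extraction 10.5.1.1 per the file headers. Per the file headers, the processed signals were background-subtracted, spatially detrended and dye-normalized within each array by a linear and a lowess step, and the authors did not scale the arrays to each other in these files. The log ratio column of the deposited files is the log10 of the red over the green processed signal. A deposited value table of the series holds log2 ratios, which equalled the log2 of red over green processed signal of the scanner files to within 5e-10, for the 36911 tiling probes only. The scale and direction of that table were settled by this comparison, and it was not centred, with column medians of -0.0188 and -0.0546. The authors' processing beyond the scanner software is not given in the sources used here.

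Each array had 45220 spots, of which 1417 were control spots and were left out. Spots with a non-uniformity or population outlier mark in either channel were left out as well: 1011 spots (2.31%) on replicate 1 and 35 (0.0799%) on replicate 2. On replicate 1 these marks covered 9.21% of the spots in the last 20% of the slide's rows. Repeat spots of a probe were averaged. Removing probes with no unmarked spot on an array left out 852 of 40204 probes. The planned filter on the reference channel removed 0 probes. The log2 ratio of processed Cy5 over Cy3 was centred on its median on each array. The medians before centring were -0.0200 on replicate 1 and -0.0536 on replicate 2. No loess or quantile normalization was applied beyond the lowess dye step that the processed signals already carry per the file headers.

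An intercept was fitted to the 2 ratios of each probe with limma 3.58.1 in R 4.3.3, with the empirical Bayes variance prior (2.77 prior and 1 residual degrees of freedom), and the mean was tested against 0, two-sided. The p-values were adjusted by the Benjamini-Hochberg method over 39352 probes. An enriched probe had an adjusted p under 0.05 and a mean log2 ratio of 1 or more. With 1 residual degree of freedom, the adjusted p rests largely on the variance prior. Values with ± are the SD over the 2 arrays.

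Probe names are serial numbers with no coordinates: 18462 forward, 18449 reverse, 3278 gene-style and 15 ic probes. What the gene-style and ic names stand for is not given in the sources used here. None of the names was found in the gene table at hand, which is of another strain and was not used. A genome of strain R was not used here. The design had set regions as adjacent enriched probes within a set distance in bp, and had set that none be made without positions. The numbering was found to carry the order of the chromosome, so runs of at least 3 enriched probes, consecutive in number among the probes kept on 1 strand, were used in place of that rule. A run could thus pass over a probe left out for outlier marks. This change was made after the data were seen. Neighbouring probes of the forward set correlated at 0.792, and probes 1000 numbers apart at -0.01. The reverse numbering ran opposite to the forward: over 45 windows of 800 numbers, the median correlation between the strands was 0.797 with opposite directions and 0.110 with the same direction. The shift between the strands was the same to within 1 number on both arrays in 45 of 45 windows. Runs of both strands no more than 2 numbers apart were merged into a locus, whose summit is the probe with the highest mean log2 ratio.

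The rule for naming, set before the data were examined, was the 30 loci with the highest summit, each named by its gene. With no gene assignment possible, 2 summits are given by probe name and the other loci by their position. The tests planned on gene lists, on gene starts and on the sequence under the loci need coordinates and were not run. The calling of loci was tested on simulated data. The simulation covered 39352 probes with 50 loci of each known height. The calling recovered 31 of 50 loci at a summit log2 ratio of 1.5, 46 at 2, 50 at 3 and 50 at 5. False loci numbered 0, which was fixed in advance because the background was drawn from unenriched probes alone. The simulated difference between the arrays was drawn from loci that had passed the rule. With no p threshold, the 30 real loci with a summit under 3 differed by a median of 1.28. The recovery may therefore not hold for weak loci of the real data. Alternatives tried were normexp background correction (offset 50), the deposited value table, centring on the mode, loess, scaling between arrays, filters on dim probes, fold and p thresholds, run length, another variance prior and each array alone. Permutation tests used fixed seeds. The processed files contain spot medians in place of the planned means, so normexp was run on the medians. Figures were drawn with matplotlib 3.10.9.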

Results

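The binding of GntR1 to the chromosome was measured in the soil bacterium Corynebacterium glutamicum R, an actinobacterium used for industrial amino acid production. GntR1 is a transcriptional regulator of the GntR family with known roles in gluconate use and the pentose phosphate pathway. The strain carried a FLAG-tagged gntR1, and cells growing exponentially on rich medium with 2% glucose were cross-linked with formaldehyde. DNA bound by the tagged protein was recovered with an anti-FLAG resin and hybridised against DNA of the same extract that had not been immunoprecipitated, a design known as ChIP-chip. There were 2 biological replicates, each on 1 two-colour array with the immunoprecipitated DNA in Cy5 and the reference DNA in Cy3. Each array held 40204 different probes, of which 39352 were measured without an outlier mark on both arrays. The median spot signal over its local background was 30153 in Cy3 and 52295 in Cy5 on replicate 1, and 39860.5 and 77648 on replicate 2. No spot was saturated and no spot failed to stand well above background on either array by the scanner software's marks. The number of arrays limits the precision.

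The question put by the design was where on the chromosome the tagged regulator was bound. The ratio of immunoprecipitated over reference DNA was raised at 513 of 39352 probes, or 1.30%. The rule was a mean log2 ratio of 1 or more and an adjusted p under 0.05 in limma. The enriched probes comprised 248 of 18033 probes of the forward tiling set, 228 of 18033 of the reverse tiling set and 37 of 3271 probes with gene-style names. None of the 15 probes of a small further set, which the files name with the letters ic, was enriched. Their mean log2 ratios lay between -0.20 and 0.29. The median log2 ratio of the enriched probes was 2.67, with 351 of them at 4-fold or more, 125 at 16-fold or more and 13 at 64-fold or more. The adjusted p lay between 0.04 and 0.05 for 246 of the 513 probes, so the number called was sensitive to the threshold, and 170 had an adjusted p under 0.01. The count was 271 with mode centring, 261 with a trended robust variance prior, 794 with the arrays scaled to one median absolute deviation, 1233 with normexp (347 of the 513 shared) and 825 with no p threshold, and replicate 2 alone gave 1213 probes at 2-fold.

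The enriched tiling probes gathered in 38 narrow loci, defined as runs of at least 3 enriched probes consecutive in number among the probes kept. These loci held 403 of the 476 enriched tiling probes (84.7%) and together spanned 1.26% of the forward numbering. Both strands carried a run at 37 of the 38 loci, and the remaining locus had a run among reverse probes alone. The median locus spanned 6 probe numbers and held 11 enriched probes over both strands. Summit enrichment ran from 6.39-fold to 306-fold with a median of 27.9-fold. The highest forward and the highest reverse probe of each locus were related across loci (Pearson r = 0.798, Spearman rho = 0.852, over 38 loci, which are not independent replicates). Probe numbers followed the order of the chromosome, as described with the processing, but the files used here pair no probe with a gene or a coordinate. Each locus is therefore placed by its percent of the forward numbering, and gene names were not assigned.

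The strongest locus had its summit at probe CGRrev01469, at 92.0% of the numbering, with a log2 ratio of 8.26 ± 0.37 (SD, n = 2), which is 306-fold (adjusted p = 0.000841). It held 13 enriched probes. The next locus, with its summit at CGRfwd09071 near the middle of the numbering (49.1%), reached 7.23 ± 0.41 (SD, n = 2), or 151-fold (adjusted p = 0.00141), and held 11 enriched probes. The values belong to different probes, so no order between the loci was tested. Size and order also depended on the processing. With normexp, run on unprocessed spot medians, these summits had log2 ratios of 2.48 and 2.37. The highest of the 30 strongest loci was then the one at 67.1% of the numbering with 3.70. Another 5 loci exceeded 64-fold. The locus at 81.7% reached 6.96 ± 0.18 (SD, n = 2), the locus at 79.8% reached 6.72 ± 0.20 and the locus at 65.7% reached 6.30 ± 0.34. The loci at 50.6% and 96.9% reached 6.26 ± 0.32 and 6.19 ± 0.71. The locus at 81.7% was also compact, with 7 enriched probes over both strands.

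A further 20 loci had summits between 16-fold and 64-fold, and 11 had summits between 4-fold and 16-fold. Among the 30 strongest loci the weakest summit was 3.73 on the log2 scale, or 13.3-fold, at 67.1% of the numbering, and the median summit was 5.43, or 2.58 with normexp. The weakest of all 38 loci lay at 14.3% of the numbering with a summit of 2.68 ± 0.86 (SD, n = 2), or 6.39-fold (adjusted p = 0.0480). Summit adjusted p in limma was under 0.01 at 16 loci and above 0.04 at 13 loci. Along the numbering, 6 loci lay below 15%, none between 15% and 30%, 3 between 30% and 45%, 8 between 45% and 60%, 9 between 60% and 80% and 12 above 80%. Summits of 16-fold or more occurred in each of the stretches that held a locus. The number of loci depended on the rule for a probe: 13 loci were left at an adjusted p under 0.01 and 22 when the arrays were centred on their mode, while 67 were found by a mean of 2-fold with no p threshold. Replicate 2 alone gave 98 loci and replicate 1 alone 43.

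**Figure D1:**
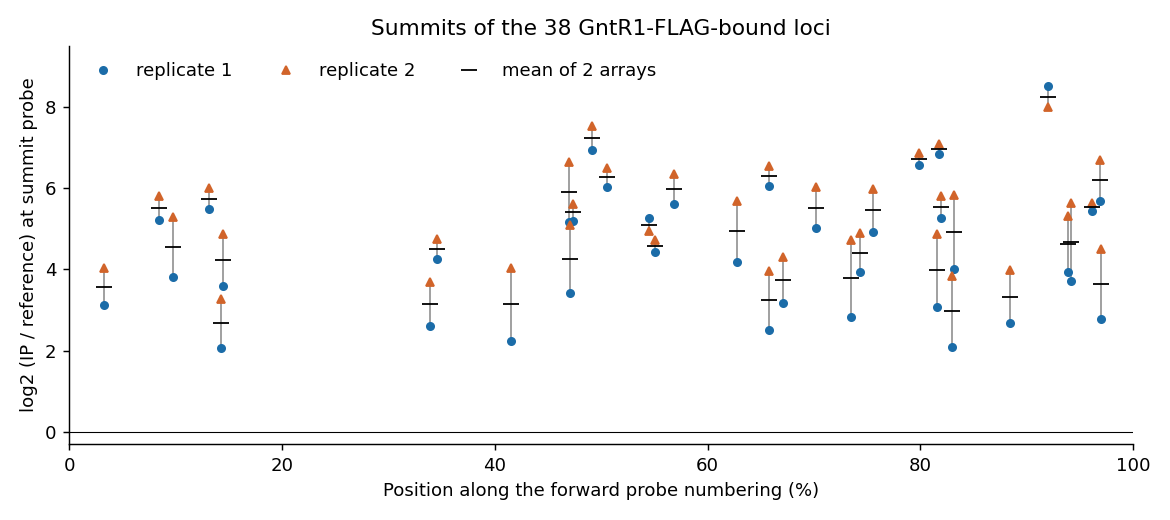
Summit log2 ratio of immunoprecipitated over reference DNA (vertical axis) at each of the 38 bound loci against the percent of the forward probe numbering (horizontal axis); circles are replicate 1, triangles replicate 2, dashes their mean and grey lines join the arrays. Summit means run from 2.68 to 8.26, no locus lies between 15% and 30%, and replicate 2 is the higher array at 36 of 38 summits.

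Around the summits the signal fell off over a few probes on either side. The mean log2 ratio over the 38 loci, with both strands averaged, was 4.38 at the summit position. At 1 number to either side it was 3.57, over the 37 loci with a probe there, and 3.32. It was 2.47 and 2.15 at 2 numbers, 1.33 and 1.09 at 3 numbers, and 0.57 and 0.52 at 4 numbers. At 5 numbers it was 0.28 and 0.24. The shape was alike on both arrays, with a summit mean of 3.92 on replicate 1 and 4.84 on replicate 2.

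**Figure D2:**
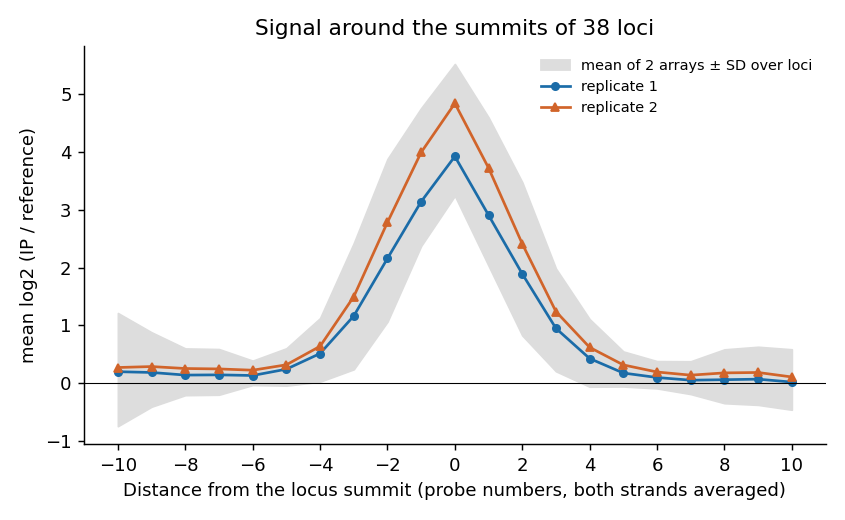
Mean log2 ratio of immunoprecipitated over reference DNA (vertical axis) by distance from the summit in probe numbers (horizontal axis), over 38 loci (37 at a distance of -1) with both strands averaged; lines are the arrays and the grey band is the mean of both arrays ± SD over loci. The mean falls from 4.38 at the summit to 0.57 and 0.52 at 4 numbers to either side.

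The probes with gene-style names were printed in repeat and separate from the tiling sets. They were hybridised with the same DNA on the same arrays, so they are no independent evidence of binding. Their positions were not compared with those of the loci. Of 3271 such probes, 37 were enriched (1.13%). The highest had a log2 ratio of 6.47 ± 0.31 (SD, n = 2), or 88.8-fold, and the next 6.09 ± 0.11, or 68.0-fold. Among the 37, 17 had an enriched probe of the preceding or following number, against a median of 0 and a highest of 8 in 10000 random draws of 37 probes (permutation p = 1e-04, one-sided, the smallest these draws can give).

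Signal of 2-fold or more in the opposite direction was scarce. The same rule applied to a mean log2 ratio of -1 or less marked 1 probe of 39352, a reverse tiling probe with a mean of -1.17. It gave 0 depleted loci in limma, and also 0 at an unadjusted p under 0.05. Small shifts were not scarce: with no fold threshold, 1873 probes were lower and 1751 higher at an adjusted p under 0.05, the lower ones with a median log2 ratio of -0.38. That split depended on the processing, with 15 lower and 303 higher when the arrays were centred on their mode, and 0 lower and 1575 higher with normexp. An untagged or mock immunoprecipitation was not analysed here, and depleted loci do not measure false calls in the enriched direction.

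Across 39352 probes, which are not independent replicates, Pearson's r between the arrays was 0.927 and Spearman's rho 0.831, and r was 0.560 with normexp. Over the 34504 tiling probes outside the bound loci and 8 numbers either side, r was 0.845 and rho 0.822. Those probes still included weaker loci that were found only with no p threshold. A dye effect common to both arrays could also add to r. The median SD between arrays was 0.06 on the log2 scale, against 0.03 between repeat spots of a gene-style probe within either array. At bound probes the arrays differed by more. Of the 513 enriched probes, 471 were higher on replicate 2, by a median of 0.69, and the median SD at the 38 summits was 0.73. All 43 loci that replicate 1 gave alone were found on replicate 2. The 55 loci found on replicate 2 alone were above 0 on replicate 1 in 55 of 55 cases, with a median log2 ratio of 0.68 there against 1.67 on replicate 2.

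**Figure D3:**
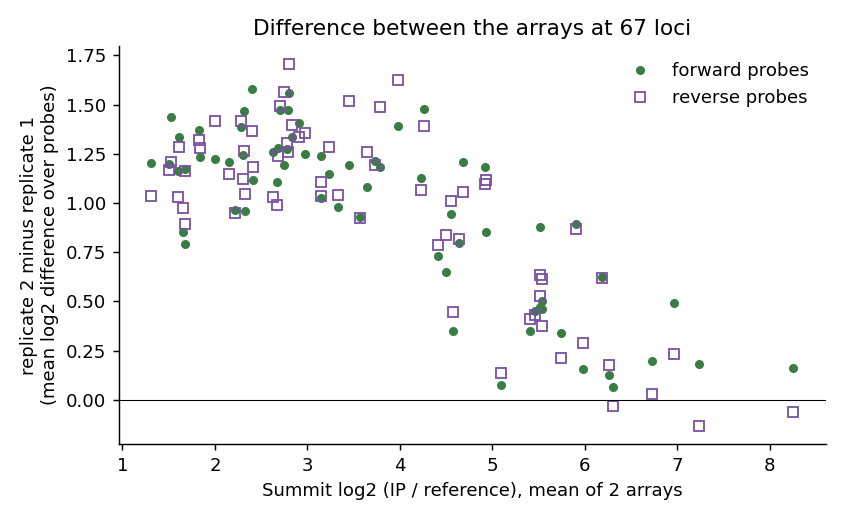
Mean log2 ratio of replicate 2 minus that of replicate 1 over the probes of a locus (vertical axis) against the locus's summit log2 ratio, mean of both arrays (horizontal axis), at the 67 loci found by a mean of 2-fold with no p threshold; filled circles are forward probes and open squares reverse probes. The median difference is 1.28 at the 30 loci with a summit under 3 and 0.34 at the 17 loci with a summit of 5 or more.

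The high ratios arose from both channels, with the larger part in the reference channel. At probes with a log2 ratio of 5 or more, the median processed Cy3 signal was 4.46% of its level at probes between -0.5 and 0.5 on replicate 1 and 4.33% on replicate 2. The median Cy5 signal was 2.10-fold and 2.20-fold of its level there. The sum of both processed signals was 1.07-fold and 1.11-fold.

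**Figure D4:**
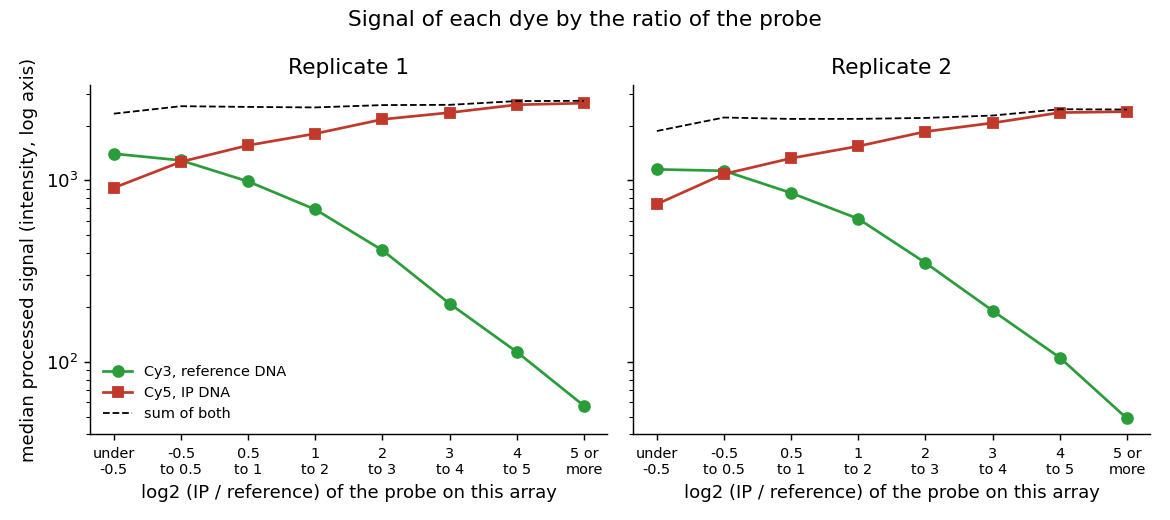
Median processed signal of Cy3 (reference DNA), of Cy5 (immunoprecipitated DNA) and of their sum (vertical log axis, intensity) over probes grouped by their log2 ratio on the same array (horizontal axis), one panel per replicate. Cy3 falls to 4.46% and 4.33% of its unenriched level in the highest group while Cy5 rises 2.10-fold and 2.20-fold.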

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

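The alternatives with outlier spots kept, no p threshold at a mean of 2-fold, and either strand alone were chosen after seeing the data, as was the definition of a locus by consecutive numbers. Main counts were 513 enriched probes and 38 loci. Counts stayed within 1.5 times of these with the deposited value table, loess, outlier spots kept, fold thresholds of 1.5 to 4, runs of 2 or 5 probes, 2-fold on both arrays and either strand alone, with 29 to 51 loci. Filters on dim probes removed 0 probes and test nothing, and loess tests little, since the processed signals already carry a lowess dye step. Counts moved further with normexp (1233 probes, 61 loci, 34 of the 38 shared), mode centring (271 and 22), equal median absolute deviation (794 and 65, all 38 shared) and a trended robust variance prior (261 and 19); the cause was not tested. An adjusted p under 0.01 left 170 probes and 13 loci, and dropping the p threshold at a mean of 2-fold gave 825 and 67, by construction of the rule. Each array alone, with no test, gave 534 to 1213 probes and 43 to 98 loci, the lower values without replicate 2 and the higher without replicate 1. The median summit of the 30 strongest loci was 5.43 and ranged from 5.10 to 5.74 with 1 array left out, and was 2.58 with normexp. With normexp 1 of the 30 summits, at 55.0% of the numbering, no longer passed (log2 ratio 1.24, adjusted p = 0.0651; 0.000878 to 0.00106 with loess and the value table). Depleted loci numbered 2 at 1.5-fold, and 0 at 3-fold and with normexp. The correlation between arrays was 0.560 with normexp and 0.845 outside the loci. No paired analysis was possible because there was 1 group only. Other gap lengths in bp, the correction for probe GC content, and the alternatives for gene starts, gene lists and sequence were not run, since they need coordinates or sequences. Every spot was well above background by the scanner software's marks. The median summit was smaller with normexp, which also started from unprocessed spot medians. Without normexp, spot medians over local background still differed widely between the 125 probes of 16-fold or more and unenriched probes. Cy3 was lower by 3.61 and 3.99 on the log2 scale on replicates 1 and 2, and Cy5 higher by 1.00 and 1.03. These values argue against the unprocessed medians as the source of the smaller ratios at those probes. Which part of normexp lowered the summits was not tested.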

Other observations

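The tests in this part were chosen after the result was seen, other than the test of a brightness trend across the slide for the tiling probes.

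The bound loci were unevenly spread. Of the 38 loci, 15 had another locus within 50 numbers, against a median of 7 in 10000 random placements (permutation p = 0.013, one-sided). The longest stretch without a locus ran from 14.4% to 33.9% of the numbering, or 19.5% of it, against a random median of 10.6% (permutation p = 0.012, one-sided). With the 67 loci found by a mean of 2-fold and no p threshold, 24 had such a neighbour against a random median of 20 (permutation p = 0.24), and the longest stretch was 7.01% against 6.85% (permutation p = 0.46), so neither feature held for the wider set. The difference between the sets was not tested.

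A summit near 3% of the numbering was enriched with no shoulder. Its highest probe, of the reverse set, had a log2 ratio of 3.96 on replicate 1 and 4.12 on replicate 2. Within 2 numbers, over both strands, only 2 probes had a mean log2 ratio of 1 or more, the highest probe itself included. A bound locus had its summit close by, at 3.27% of the numbering. Probes 2 to 3 numbers away averaged -0.04, or -1.02% of the summit, against a median of 25.8% over 81 summits with a mean log2 ratio of 1.5 or more. Of these summits, 2 were under 10%, the other being the bound locus at 81.7% of the numbering with 7.18%. The run was too short to count as a locus, and the summit was picked out after its values were seen.

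The reference signal was lower at enriched probes than at the rest. At the 125 probes of 16-fold or more, the unprocessed Cy3 signal fell by 3.61 on the log2 scale on replicate 1, the array with the smaller fall, which argues against the scanner software's processing. The unprocessed Cy5 signal at these probes rose by 1.00 on the array with the smaller rise. The probes were chosen by their ratio, so with such a Cy3 fall a rise in Cy5 largely followed from the choice. It therefore cannot decide whether probes that bind both dyes poorly had a part. The sum of both processed signals was 1.11 times its level at unenriched probes on the array farther from 1. An unchanged Cy3 signal would have given 12.8 and 19.0 on the arrays. Processed signals carry a dye normalization, and the unprocessed sum, which was not tested, rose more by its parts. At a log2 ratio of 5 or more, the unprocessed medians on replicate 1 were 1449 in Cy3 and 105582 in Cy5. Between -0.5 and 0.5 they were 30678.5 and 52479. On replicate 2 they were 1997 and 156784, against 40968.8 and 77139. A candidate explanation is still that DNA of both dyes competed for a limited number of probe molecules in a spot, and no biological explanation was tested.

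The excess of replicate 2 over replicate 1 differed between loci and was shared by their strands: over the 67 loci, forward and reverse differences correlated at r = 0.945 (Spearman rho = 0.892). One overall difference in immunoprecipitation yield, acting alone and without compression of high ratios, would raise the difference with the height of the summit. The relation ran the other way (Spearman rho = -0.649), which argues against such a yield difference as the whole cause. After a quadratic fit on summit level the strands still correlated (r = 0.859, permutation p = 1e-05, the smallest 100000 permutations can give, and 0.855 without the 2 loci farthest from the median level). The fit removed the summit level alone and both strands share the peak, so this cannot decide on compression by level. Probes with a mean log2 ratio of 1 to 2 were also compared. Their median difference was 0.20 over 45 probes at loci with a summit of 5 or more. It was 1.13 over 145 probes at loci with a summit under 3. Probes of like level thus differed by locus, which argues against compression by level as the whole cause. At the highest probe of each strand, where fragment length matters least, the residual correlation was 0.556 (permutation p = 1e-05), which argues against longer fragments on 1 array as the whole cause. Each cause was weighed alone, so a combination of them stays open. So does a difference between the extracts or their amplification that may be particular to each locus. With 1 group, no biological explanation was tested.

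The signal of unenriched probes after the scanner software's background subtraction was lower in the middle of the numbering than at its ends. This held in both dyes, on both arrays and in the forward, reverse and gene-style sets, by 0.10 to 0.27 on the log2 scale. Row and column medians of the slide were taken out of another signal, the spot median over its local background. The falls were then 0.149 to 0.199 for the tiling probes, and 0.122 and 0.136 for the gene-style probes on replicate 2. This argues against a brightness trend across the slide as the whole cause there. On replicate 1 the gene-style falls were 0.088 in Cy3 and 0.071 in Cy5, the latter with a spread of 0.037 between neighbouring stretches. That value alone does not decide on such a trend. Probe number correlated with slide row and column at 0.003 and -0.001 in that set, and at -0.008 to 0.011 in the tiling sets. So small a linear correlation leaves such a trend little room, but does not exclude a curved relation. More DNA copies near the replication origin of dividing cells could give such a fall, and the falls in Cy5 and Cy3, each averaged over the forward, reverse and gene-style sets, differed by at most 0.065 on an array. A gradient of probe base composition could give it as well, and the largest fall of 0.27 was not corrected for it because probe sequences were not used here. These 2 explanations cannot be told apart, and the place of the origin in the numbering is unknown here.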
